A study of Mus musculus with 21 samples.

How the data were processed

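RNA was taken from Myc-CaP cells and from tumours grown from them in FVB mice, in 21 libraries of polyadenylated RNA, prepared with a stranded kit and sequenced as paired reads of 50 bp, per the labels' protocols. The authors deposited gene-level estimated counts, which need not be whole, as a plain table and as a table scaled by transcript length. Both hold 45706 genes, and 7.96% to 10.2% of the values in a library were not whole numbers. Per the submitters' processing notes, Trim Galore 0.6.7, STAR, Salmon 1.5.2 and the GRCm38 build were used; their settings are not given in the sources used here. Of the gene IDs, 45143 were found in GENCODE M21, from which positions were taken.

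The estimated counts of the plain table were rounded to whole numbers. Genes were kept by filterByExpr, scaled by TMM and tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Each adjusted p given for a gene is from that test. A count of changes of 2-fold or more is given besides. KO against WT was fitted by genotype within cells and within tumours, the interaction on all 21 libraries, and differences among KO lines by an F test over 3 lines. Fold changes of genes with 0 counts in a group depend on the prior count of the fit and are no bounds; 3 counts were taken as the floor of a count of 0, which covers counting error only. Levels of groups are CPM with TMM scaling over the libraries of the comparison, and levels of single libraries are CPM with TMM scaling over all 21 libraries. Log2 CPM used a prior count of 2. In the tests of explanations 0.1 CPM was added before taking log2. Genes that part KO from WT there were changed 4-fold or more in KO cells, with all KO1 and KO2 tumours beyond the range of WT tumours and the means 2-fold or more apart; KO3 tumours were not used to choose them.

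The gene lists, 32 in number, were written before the data were examined, as were the tests, the rule for named genes and the alternatives other than those named below as added. Lists with at least 5 tested members were tested with camera of limma 3.58.1 at its preset correlation of 0.01, and again with an estimated correlation and with fry, which tests whether a list moves on balance and does not compare it with other genes. The lists of B and plasma cell markers and skin keratinocyte markers had too few tested members in KO against WT. List scores are the mean log2 CPM of the members and were compared by exact permutation. Genes always named, where tested, included Ern1, Xbp1, Dnajb9, Hspa5, Ddit3, Myc, Irf7, Cxcl9, Cxcl10, B2m, H2-K1, Cd274, Ptprc and Cd8a. For KO against WT the 10 largest rises and 10 largest falls were named among genes past the threshold with a mean log2 CPM of at least 2, the same sign in each line and a symbol that is not a predicted or clone name. In each list that passed, the 3 members with the smallest p were named, and in other comparisons the 5 genes with the smallest p per direction. Some genes that these rules select are not reported here. Cd8a passed no filter.

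Replicates are separate samples in the labels, and nothing used here says that the cell libraries came from separate cultures, so that p-values measure the spread between these libraries. KO libraries of 3 lines and WT libraries of 1 line were compared, so the line is not replicated in WT. No pair of replicates agreed within sampling noise: the lowest chi-square per degree of freedom was 8.39.

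Alternatives were RLE scaling, DESeq2 1.42.0, no filter, the length-scaled table, the lines as groups, libraries summed per line, limma voom with the line as a random block, the replicate number as a block, leaving out each library and each KO line, WT tumours 3 and 4 summed because their descriptions share a number, and a leukocyte covariate. Chosen after seeing the data were a covariate of Y-linked genes, fits without WT tumours 1 and 4, the interaction without KO3, and list scores with WT tumours 3 and 4 as 1 unit. Where leaving out a library left 1 WT cell library, that library was assumed to vary like the others. The steps were tested on simulated data made from the real means, with 100 genes changed by 1 and another 100 by 2 on the log2 scale. Of those changed by 1, 84% were recovered in cells (12254 genes) and 78% in tumours (14200 genes). Of all calls, 6.67% and 3.31% were false. Changed genes were drawn from those with a mean of at least 1 CPM, so recovery among lower genes was not measured. Recovery was 53% for the interaction, 95% and 60% for line differences in cells and tumours, and 27% for WT tumours against cells. Libraries were simulated independently, without the likeness within a line, so these rates do not cover the spread between lines. Figures were drawn with matplotlib 3.10.9. No column of the tables was left out.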

Results

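Gene expression was measured by RNA-seq in Myc-CaP cells, a mouse prostate cancer line driven by a Myc transgene, and in tumours grown from them in FVB mice. The cells were wild type (WT) or carried a CRISPR knockout (KO) of Ern1, the gene of IRE1α, an endoplasmic reticulum (ER) stress sensor whose RNase splices Xbp1 mRNA into the form that encodes the transcription factor XBP1s. There were 3 KO lines, here KO1, KO2 and KO3, and 1 WT line. The 8 cell libraries comprised 2 WT and 2 of each KO line, and the 13 tumour libraries comprised 4 WT and 3 of each KO line. Total counts ran from 18105538 to 25068254 in cells and from 15994285 to 27497796 in tumours. In WT tumour replicate 4 the gene Yam1, which shares its locus with a ribosomal RNA gene, took 24.0% of the counts, against 6.16% to 8.47% in the other tumours.

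The targeted gene was examined first. The guide GCTTGCATGCTGTTAGCAAG matched exon 2 of Ern1 (ENSMUSG00000020715), in the coding sequence, on chromosome 11 at 106458942 to 106458961 in GRCm38, and was followed by AGG in the transcript. Ern1 mRNA was present in every group. In cells its level was 129 ± 11.7 CPM in WT (SD, n = 2), and 185 ± 12.7, 203 ± 0.767 and 183 ± 6.98 CPM in KO1, KO2 and KO3 (SD, n = 2 each). The log2 fold change was 0.56 ± 0.09 (SE), with an adjusted p of 0.00341 by edgeR. In tumours it was 72.7 ± 8.25 CPM in WT (SD, n = 4), and 82.2 ± 6.37, 79.8 ± 8.04 and 60.8 ± 3.73 CPM in KO1, KO2 and KO3 (SD, n = 3 each), and did not pass, with a log2 fold change of 0.03 and an adjusted p of 0.914 by edgeR. A gene-level count does not read a small insertion or deletion, so these values check nothing about the edit.

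The first comparison asked what loss of IRE1α changed in cultured cells. Targets of XBP1s and of ATF6, another ER stress factor, were lower in KO cells. Of 36 XBP1s target genes, 34 fell and none rose (34 fell adjusted over the list alone), with a median log2 fold change of -1.36. Sec24d, a coat protein of vesicles leaving the ER, went from 159 ± 5.06 CPM in WT (SD, n = 2) to 31.3 ± 3.08 CPM in KO (SD, n = 6), a log2 fold change of -2.35 ± 0.09 (SE). Spcs2, a signal peptidase subunit, fell by 1.66 on the log2 scale, Surf4, a cargo receptor, fell by 1.38, and Dnajb9, a co-chaperone of the ER, fell by 1.45. The list had an adjusted p of 1.27e-33 by camera with its preset correlation (adjusted p = 0.00791 with an estimated correlation). Of 12 ATF6 target genes 10 fell (10 adjusted over the list alone), among them the chaperones Hyou1 and Hspa5 and the disulfide isomerase Pdia4, with log2 fold changes of -1.39, -1.31 and -1.22. The adjusted p of that list was 1.31e-08 (adjusted p = 0.0129 with an estimated correlation). Hyou1, Herpud1 and Creld2 are on both the XBP1s and the ATF6 list, so the lists are not fully separate evidence.

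Cholesterol synthesis genes were lower as well in KO cells. Of 22 members 15 fell (16 adjusted over the list alone), among them Cyp51 at -0.91 ± 0.10 log2 (SE) and Lss at -0.67. The list had an adjusted p of 2.42e-10 by camera (adjusted p = 0.432 with an estimated correlation). Of 16 hypoxia and glycolysis genes 6 fell (8 fell and 1 rose adjusted over the list alone), including the glucose transporter Slc2a1 at -0.44, P4ha1 at -0.50 and Pdk1 at -0.58. Their adjusted p was 0.00306 by camera (adjusted p = 0.530 with an estimated correlation). Of 24 proliferation genes 9 rose (18 adjusted over the list alone), including Foxm1 at 1.12 and the replication factors Mcm7 and Mcm6 at 0.59 and 0.50. Their adjusted p was 6.31e-07 by camera (adjusted p = 0.641 with an estimated correlation). None of the 25 ATF4 target genes passed over all genes or adjusted over the list alone, and the smallest p were those of Ppp1r15a, Cars and Trib3, at 1.09, 0.63 and 1.72. That list had a median of 0.45 and an adjusted p of 0.0462 by camera (adjusted p = 0.812 with an estimated correlation). Its medians were 0.73 in KO1, 0.79 in KO2 and -0.23 in KO3.

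Outside the lists, Akr1c18, a steroid-metabolising enzyme, went from 16.7 ± 1.18 to 0.0613 ± 0.0653 CPM (SD, n = 2 and 6), and Bhlha15, a transcription factor of secretory cells, from 16.3 ± 2.41 to 0.411 ± 0.138 CPM. Mga went from 17.0 ± 0.402 CPM to 0 counts in all 6 KO libraries, at least 655-fold lower without TMM scaling, against a floor of 3 counts over the 6 libraries. Stra6, a retinol transporter, went from 101 to 1.82 CPM and Xdh, xanthine dehydrogenase, from 72.4 to 7.39 CPM. The other largest falls were in Sema5a, the collagens Col4a1 and Col4a2, Cyp2b10 and Adh1, with log2 fold changes of -3.66, -3.11, -2.97, -2.91 and -2.58. The largest rises were in Vil1 at 2.66 ± 0.78 log2 (SE), Pdzd7 at 2.28, Kctd12b at 2.10, Sdpr at 2.09 and Notch1 at 2.08, followed by Fam171b, Usp11, Steap3, Tfcp2l1 and Palm. Myc, Irf7, Cd274, B2m, H2-K1 and Ddit3 did not pass. Xbp1 itself was at 116 ± 1.49 CPM in WT (SD, n = 2) and 74.1 ± 18.3 CPM in KO cells (SD, n = 6), with an adjusted p of 0.0668 by edgeR.

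In all, 1808 of 12254 genes passed an adjusted p of 0.05 by edgeR in KO cells, 612 higher and 1196 lower, 354 of them by 2-fold or more. All 1808 had the same sign in each KO line, against 56.3% of the genes that did not pass. The pooled fit itself favours genes whose lines agree, so this share is no separate evidence of agreement. There is 1 WT line, and with libraries summed per line 38 genes passed, 37 of them lower. Without WT cells replicate 1 the count was 378, without replicate 2 it was 428, and without line KO3 it was 4315. The XBP1s target score differed by -1.30 between KO and WT cells (exact two-sided permutation p = 0.0357, the smallest possible over 28 splits, 0.173 adjusted over 34 scores).

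**Figure D1:**
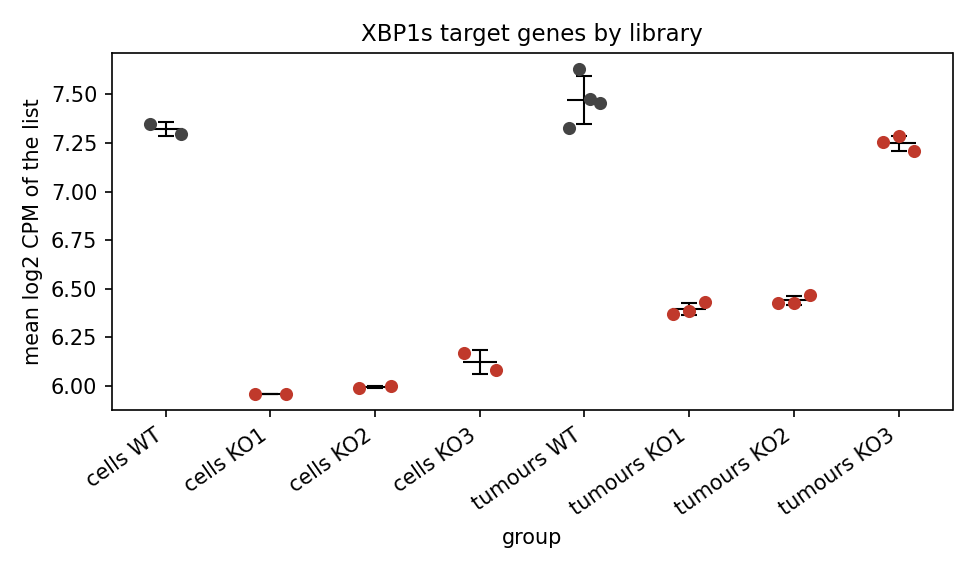
Mean log2 CPM of the 36 XBP1s target genes (vertical axis) in each library, by group (horizontal axis). Points are libraries and bars show the mean and SD of the group; KO3 tumours averaged 7.25 against 6.40 in KO1, 6.44 in KO2 and 7.47 in WT tumours.

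The second comparison asked what loss of IRE1α changed in tumours. XBP1s target genes were again lower. Of 36 members 12 fell (31 adjusted over the list alone), with a median of -0.67. Edem1, which directs misfolded proteins to degradation, went from 247 ± 59.9 CPM in WT (SD, n = 4) to 121 ± 36.9 CPM in KO (SD, n = 9), a log2 fold change of -1.02 ± 0.21 (SE). Txndc11 fell by 1.07 and Ssr3 fell by 0.91 on the log2 scale. The list had an adjusted p of 1.40e-20 by camera (adjusted p = 0.430 with an estimated correlation), and medians of -0.9996 in KO1, -0.96 in KO2 and -0.22 in KO3. Dnajb9, at a log2 fold change of -1.18 ± 0.35 (SE), had an adjusted p of 0.0756 by edgeR. Hspa5, Xbp1, Ddit3 and Myc did not pass either.

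Interferon-stimulated genes were higher in KO tumours. Of 34 type I interferon-stimulated genes 6 rose (24 adjusted over the list alone), with a median of 0.56. Ifit1 went from 10.5 ± 0.938 CPM in WT (SD, n = 4) to 18.4 ± 3.83 CPM in KO (SD, n = 9), a log2 fold change of 0.81 ± 0.16 (SE), and Ddx58, the RNA sensor RIG-I, and Herc6 rose by 0.58 and 0.74. The list had an adjusted p of 1.05e-13 by camera (adjusted p = 0.430 with an estimated correlation). Of 25 interferon-gamma-induced genes 3 rose (4 adjusted over the list alone), namely the GTPase genes Irgm1, Igtp and Irgm2, with log2 fold changes of 0.65, 0.71 and 0.69. Their list had an adjusted p of 1.32e-06 by camera (adjusted p = 0.430 with an estimated correlation). Igtp and Irgm2 overlap on chromosome 11, so the division of reads between them is uncertain. Of 18 markers of cytotoxic T and NK cells 5 were tested, and 2 rose (2 adjusted over the list alone), Gzmb and Klrk1. These went from 0.141 to 0.595 CPM and from 0.689 to 1.95 CPM. In WT tumours Gzmb lay near the floor of 3 counts, which was 0.110 to 0.181 CPM in those libraries. The list had an adjusted p of 0.000439 by camera (adjusted p = 0.430 with an estimated correlation). Irf7, Cxcl9 and Cxcl10 did not pass, with log2 fold changes of 0.51, 0.78 and 0.57 and adjusted p of 0.0708, 0.139 and 0.283 by edgeR.

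Of 19 hypoxia and glycolysis genes 3 fell in KO tumours (11 adjusted over the list alone), Pgk1, Ero1l and Adm, with log2 fold changes of -0.75, -0.66 and -2.09 (adjusted p = 0.452 with an estimated correlation). Of 8 neutrophil markers S100a9, Il1b and Clec4e fell by 5.71, 2.79 and 2.22 on the log2 scale (6 adjusted over the list alone; adjusted p = 0.682 with an estimated correlation). These falls rested on WT tumours replicate 1, where S100a9 was at 110 CPM against at most 1.40 CPM in the other WT tumours. The neutrophil marker score was 2.80 in that library and at most -0.63 in the other WT tumours. Without that library none of the 3 genes passed, and Neutrophil markers had an adjusted p of 0.885 by camera. Adm and Hba-a2 did not pass without it either. Of 5 erythroid genes Hba-a2 fell (5 adjusted over the list alone), a globin gene with a near-identical copy, so that its count is uncertain (adjusted p = 0.520 with an estimated correlation). Among 27 ATF4 target genes Sars and Mthfd2 fell (8 adjusted over the list alone), and among 12 ATF6 target genes Ero1lb fell (4 adjusted over the list alone), with adjusted p = 0.520 for both lists with an estimated correlation. Among 22 cholesterol synthesis genes Fdps fell (1 adjusted over the list alone; adjusted p = 0.630 with an estimated correlation). T cell markers, macrophage markers and proliferation genes passed by camera with medians of 0.70, 0.27 and 0.27 and no member past the threshold over all genes (adjusted p = 0.537, 0.749 and 0.800 with an estimated correlation). Adjusted over the list alone, 5 macrophage markers rose and 1 fell, and no T cell marker or proliferation gene passed. Skeletal muscle marker scores (mean log2 CPM) were 5.09 ± 0.760 in KO1, 2.91 ± 2.59 in KO2 and -1.56 ± 0.854 in KO3 tumours (SD, n = 3 each) and 1.43 ± 4.44 in WT tumours (SD, n = 4).

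Other large falls in KO tumours were in Nebl, an actin-binding protein, from 16.5 ± 5.00 to 0.342 ± 0.223 CPM (SD, n = 4 and 9), the flavin monooxygenase Fmo1, the fibrinogen chain Fga and Angptl7, with log2 fold changes of -2.28, -2.08 and -2.12 for the last 3. Rn18s-rs5, at the locus of Yam1, and the small nucleolar RNAs Snora73b and Snora73a fell by 2.64, 2.23 and 2.03, and none of these 3 passed without WT tumours replicate 4, where Yam1 stood apart. The largest rises were in Vil1, an actin-bundling protein, from 1.99 ± 0.959 to 12.8 ± 2.35 CPM, Cyp2f2, Klk1, the ciliogenesis factor Foxj1, Kcnk5, Klk1b11, Pik3r6, Xlr, Ncmap and Plch2. Klk1 and Klk1b11 belong to a family of closely similar kallikrein genes, so the division of reads between them is uncertain.

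In KO tumours 518 of 14200 genes passed by edgeR, 182 higher and 336 lower, 153 of them by 2-fold or more, and DESeq2 called 1103. All 518 had the same sign in each line, against 52.6% of those that did not pass, which the pooled fit again favours. By camera with its preset correlation 13 lists passed, and 40 of 100 splits of the tumours into 4 and 9 gave as many lists. The gene count was 344, 154, 254 and 269 without WT tumour replicates 1 to 4 in turn, and 328, 275 and 326 without KO1 replicate 3, KO2 replicate 1 and KO2 replicate 2; without WT tumours 1 and 4 together, an alternative chosen after seeing the data, it was 89. With WT tumours 3 and 4 summed, since their descriptions share a number, it was 246. Among the genes named here only Nebl, Fga, Vil1, Xlr, Foxj1, Cyp2f2, Kcnk5, Pik3r6 and Ddx58 passed with each WT tumour left out in turn. With libraries summed per line edgeR called 0 genes, with 1134 at an unadjusted p under 0.05, and no other tool was run on those sums.

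**Figure D2:**
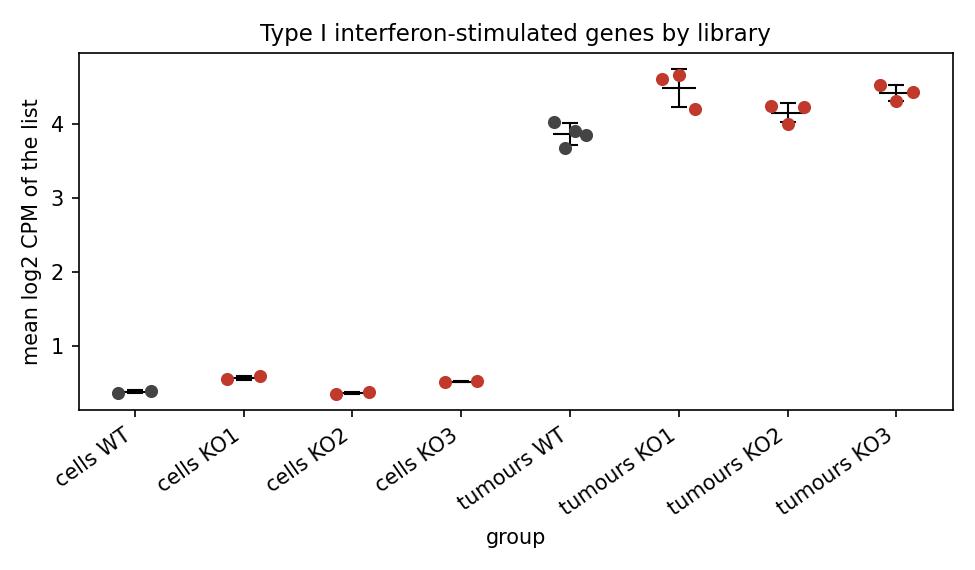
Mean log2 CPM of the type I interferon-stimulated genes (vertical axis) in each library, by group (horizontal axis). Points are libraries and bars show the mean and SD of the group; tumours averaged 3.86 in WT and 4.48, 4.15 and 4.41 in KO1, KO2 and KO3.

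List scores were compared across tumours by exact permutation over 715 splits, with adjustment over 34 scores. KO minus WT was -0.78 for XBP1s targets (exact two-sided p = 0.00140, the smallest possible, adjusted 0.0476), with all 9 KO tumours below all 4 WT tumours. The descriptions of WT tumours 3 and 4 share a number, as tumours of the same mouse might, and with these taken as 1 unit, an alternative chosen after seeing the data, the exact two-sided p was 0.00455 over 220 splits, the smallest possible, and the adjusted p was 0.124. It was 0.49 for type I interferon-stimulated genes (exact two-sided p = 0.00420, adjusted 0.0713; 0.124 with these tumours as 1 unit).

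Next it was asked which KO effects differed between tumours and cells. Several ATF6 and XBP1s targets were less reduced in tumours than in cells. Tumour libraries also held host transcripts, such as the leukocyte gene Ptprc at 0 CPM in WT cells and 17.0 CPM in WT tumours. Host transcripts were not separated from those of tumour cells, so a smaller fall in tumours need not mean a smaller effect in tumour cells. The ATF6 targets Hsp90b1, Hspa5 and Pdia4 had differences of 1.07 ± 0.22, 0.97 ± 0.22 and 1.02 ± 0.22 on the log2 scale (SE), and the XBP1s targets Manf and Ssr1 of 1.30 and 1.01. The interferon-inducible Tgtp1 also differed, by 2.20. The smallest p among genes higher in this contrast were those of Ass1, Mga, Hiatl1, Anpep and Cyp2b10, of which Mga and Hiatl1 had 0 counts in KO cells. Those among genes lower in it were Palld, Etl4, Il16, Apcdd1 and Myd88, at -1.57, -0.86, -2.59, -2.33 and -0.88. By edgeR 146 of 15173 genes passed, 131 higher and 15 lower, and 43 and 42 without WT cells replicate 1 and 2. By camera 12 lists passed with the preset correlation and none with an estimated correlation (lowest adjusted p = 0.4995).

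Differences among the KO lines were tested next. In cells the 5 genes with the smallest p were all highest in KO3. Values of single lines relative to WT were not tested each. The keratin Krt8 was at 0.45, 0.24 and 2.64 on the log2 scale in KO1, KO2 and KO3, and the complement gene C3 at 0.22, 0.57 and 3.39. Krt6a was at -1.08, -0.17 and 1.90, Tns4 at -1.70, -1.06 and 0.93, and Ceacam1 at -1.77, -1.41 and 0.41. Ddit3, a stress-induced transcription factor, was at 1.97, 1.80 and -0.34. By edgeR's F test 3713 of 12254 genes differed in cells, and 2343 and 2094 without KO3 cells replicate 1 and 2.

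In tumours the 5 genes with the smallest p among the lines were all highest in KO3 among the KO lines. Creb3l2 was at 20.7 ± 0.307, 17.0 ± 0.847 and 64.7 ± 1.503 CPM in KO1, KO2 and KO3 (SD, n = 3 each), against 60.4 ± 5.30 CPM in WT (SD, n = 4). P4hb, a disulfide isomerase, was at 648, 699.9 and 1818 CPM in KO1, KO2 and KO3 and 2097 CPM in WT, and Sec24d at 18.9, 16.5, 52.7 and 75.9 CPM in the same order. Nucb2 and Ostc, and Dnajb9 and Xbp1, also differed. By edgeR's F test 427 of 14483 genes differed. The count was 1095 without WT tumour replicate 1, 128 and 138 without KO1 replicates 2 and 3, 191, 271 and 196 without KO2 replicates 1 to 3, and 152 and 151 without KO3 replicates 2 and 3. The XBP1s target score was 0.83 higher in KO3 than in KO1 and KO2 tumours (exact two-sided permutation p = 0.0119, the smallest possible over 84 splits, adjusted 0.135). With the same exact p, ATF6 targets were 0.51 higher in KO3 and the skeletal muscle marker score differed by -5.56. KO3 was singled out of the 3 lines for these score contrasts, and the exact p does not allow for that choice.

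**Figure D3:**
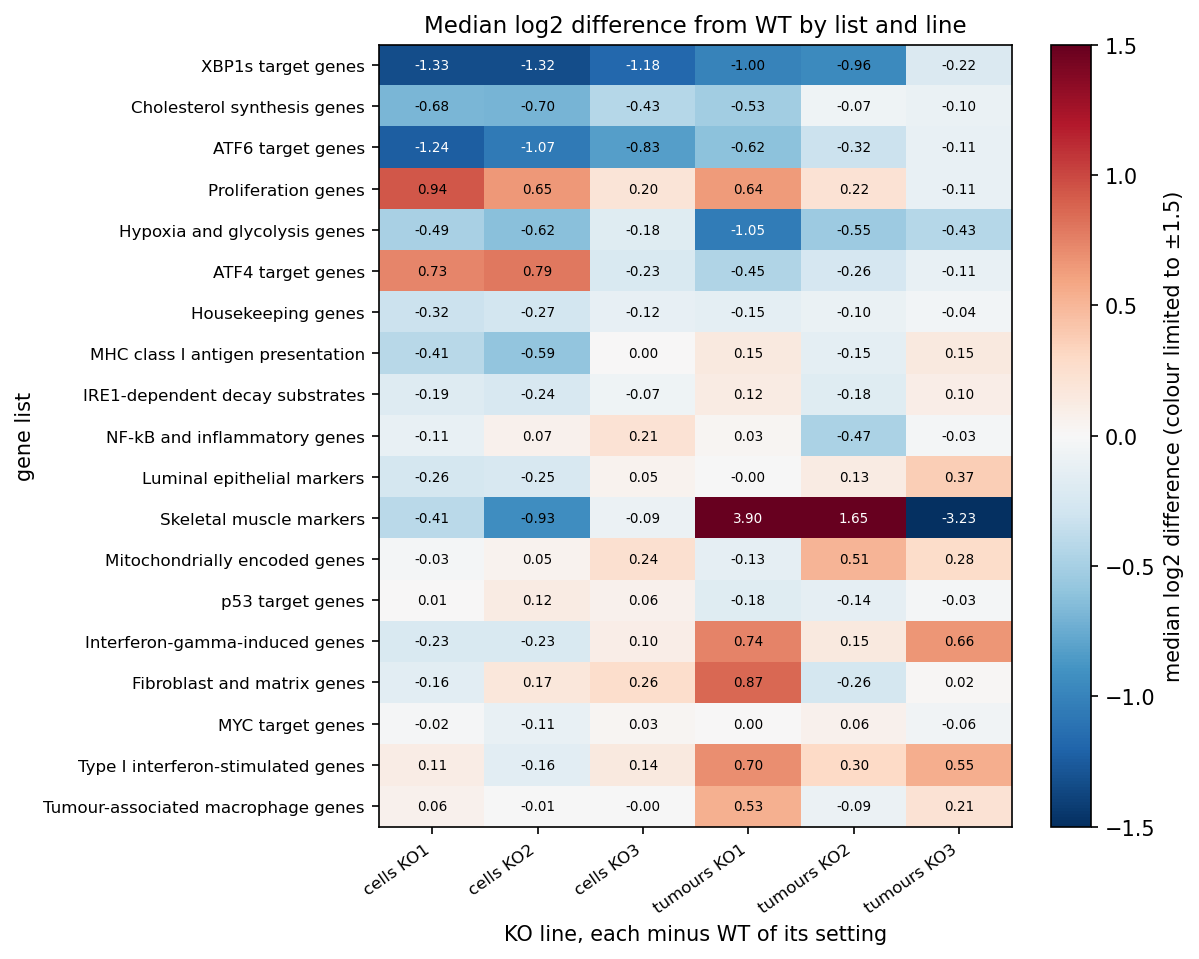
Median log2 difference from WT of gene lists tested in both settings (rows) in each KO line in cells and in tumours (columns); the printed number is the median and the colour is limited to ±1.5. XBP1s targets read -1.33, -1.32 and -1.18 in KO1, KO2 and KO3 cells and -0.22 in KO3 tumours.

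WT tumours were set against WT cells to show the setting without the knockout. Ern1 fell by 0.75 ± 0.13 on the log2 scale (SE), with an adjusted p of 0.00297 by edgeR. Vessel, macrophage and stroma genes were higher in tumours. All 15 endothelial markers, 13 of 15 macrophage markers and 16 of 18 fibroblast and matrix genes rose, and 1 macrophage marker and 1 fibroblast gene fell. Of 34 type I interferon-stimulated genes 29 rose and 2 fell, with Irf7 higher by 5.21 ± 0.27 log2 (SE). These 4 lists passed by camera (adjusted p = 0.598 for each with an estimated correlation). Mpeg1, Il18r1, Sdc3 and Lcn12 were among the rises with the smallest p, and Krt4, Rassf4, Loxl4, Itga3 and Aif1l had the smallest p among the falls. By edgeR 7159 of 14031 genes passed, 4176 higher and 2983 lower, and 3881 and 3853 without WT cells replicate 1 and 2. The median log2 change of all genes was 0.13 by edgeR and 0.41 by DESeq2.

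Genes lower in KO overlapped between cells and tumours. Among 11842 genes tested in both, 167 were lower in both, where independent lists would share 29.1 (Fisher's exact test, p = 2.35e-92). There were 24 higher in both, against 8.27 (Fisher's exact test, p = 2.34e-06). With the length-scaled counts, 127 were lower in both, against 20.8 (Fisher's exact test, p = 3.58e-70), and 9 were higher in both, against 3.76 (Fisher's exact test, p = 0.0131). Across genes, which are not independent replicates, Pearson's r of the log2 fold changes was 0.330 and Spearman's rho 0.387. Of the genes called in both, 1 was higher in cells and lower in tumours, and 7 were lower in cells and higher in tumours. The mean correlation of line differences between cells and tumours of the same line was 0.128 across 11900 genes, against 0.0351 for the next of 6 pairings (exact one-sided p = 0.167, the smallest possible).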

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

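All tests of explanations in this part were chosen after the results were seen; the counts over other splits were planned.

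Measures of the 4 WT tumours were checked for a library far from the rest, 110 checks with 10 found, where chance gives about 5.5. In WT tumour replicate 4 Yam1 took 24.0% of counts, and log2 CPM was -0.29 for Klk1b11, 7.96 for Herpud1 and -3.32 for Nkg7. In WT tumour replicate 1 the scores were 2.83 for NF-kB and inflammatory genes, 2.80 for neutrophil markers and 7.32 for MYC targets, and log2 CPM was 1.66 for Pik3r6. In WT tumour replicate 3 the housekeeping score was 8.93 and Mcm6 was at 5.69.

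The KO effect differed between tumours and cells for 146 genes. Host transcripts in the tumours were not separated, so these differences need not be those of the tumour cells. The median differences (tumours minus cells, log2) of lists that passed at the preset correlation were 0.58 for XBP1s targets, 0.76 for ATF6 targets, 0.46 for cholesterol synthesis, 0.50 for type I interferon-stimulated genes, 0.64 for interferon-gamma-induced genes, 1.33 for cytotoxic T and NK cell markers, 0.99 for T cell markers and 0.40 for MHC class I genes. They were -0.71 for ATF4 targets, -0.37 for proliferation genes, -2.25 for neutrophil markers and -0.26 for hypoxia genes. None of these lists passed with an estimated correlation (lowest adjusted p = 0.4995). Cytotoxic T and NK cell, T cell and neutrophil markers had too few tested members for a list test in KO against WT cells. In WT cells the cytotoxic and neutrophil scores were -3.27 and -3.30, near the -3.39 of the Y-linked genes, which had 0 CPM there. Their differences therefore rest mainly on the tumours. The XBP1s difference was largest in KO3, with medians in cells and tumours of -1.33 and -0.9996 in KO1, -1.32 and -0.96 in KO2 and -1.18 and -0.22 in KO3. Neutrophil markers had an adjusted p of 0.465 by camera without WT tumours replicate 1. Single genes that passed by edgeR included Hspa5 at 0.97, Hsp90b1 at 1.07, Pdia4 at 1.02, Tgtp1 at 2.20, Manf at 1.30, Ssr1 at 1.01, Ass1 at 5.87, Anpep at 1.70, Cyp2b10 at 2.30, Palld at -1.57, Etl4 at -0.86, Il16 at -2.59, Apcdd1 at -2.33 and Myd88 at -0.88. The fitted values of Mga at 9.85 and Hiatl1 at 8.75 rest on 0 counts in KO cells and are no bounds. Among the KO lines 3713 genes differed in cells and 427 in tumours.

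XBP1s targets in KO3 tumours lay near WT tumours, covering a median share of 0.814 of the way from KO1 and KO2 to WT tumours, while KO3 cells lay near the other KO cells. More host cells are argued against, since the Y-linked gene score, taken as a measure of host cells, differed by -0.12 (95% interval -0.80 to 0.57) between KO3 and the other KO tumours, and the XBP1s target score by 0.83 (0.77 to 0.89), more than that many host cells would raise any gene; less skeletal muscle as the whole cause is argued against too, since the slope of the XBP1s score on the muscle score within tumour groups predicted 0.10 (0.01 to 0.19) from the muscle difference of -5.56. WT tumours labelled as KO3 are argued against: of 327 genes changed 2-fold or more in KO cells, 41 had all 3 KO3 tumours beyond all 4 WT tumours on the KO side, the most of 35 splits of these 7 tumours (highest other 33; exact permutation p = 0.0286, the smallest possible), although 85 genes higher in KO cells exceeded WT tumours by 0.24 log2 in KO3 against 0.70 in KO1 and KO2. WT-line cells as the whole cause are argued against by 17 genes lower in KO cells and in KO1 and KO2 tumours. XBP1s and ATF6 targets were left out of these. Their median share was 0.00832 (95% interval -0.216 to 0.575), below the 0.718 that bounds the XBP1s share. The 17 were taken after the 24 genes of both directions had given 0.307 (-0.0138 to 0.782). The 7 higher in KO gave 0.939 (0.850 to 1.07), and 44 genes changed 2-fold gave 0.605 (0.470 to 0.782). Admixed WT-line cells would raise each of the 17 genes, yet 11 had all KO3 tumours beyond all WT tumours on the KO side. Nebl was at most 0.616 CPM in KO3 tumours against at least 11.4 CPM in WT tumours. Mapk13 averaged 2.11 against 29.1 CPM. For these genes the values argue against a large admixture, if such cells keep the levels of WT tumours. An admixture too small to raise these genes is not excluded. A change in IRE1α signalling of the KO3 cells in mice was not tested and stays open.

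Genes with 0 counts in all 6 KO cell libraries had counts in all 9 KO tumours. There were 7 protein-coding genes with at least 20 counts in each WT cell library, among them Mga, at least 655-fold lower in KO cells over the group. The opposite pattern was found in 0 genes. It asked for at least 20 counts in each of the 6 KO cell libraries, over 3 lines, so the counts are not like for like. A single deletion is argued against, since the 7 genes lie on 6 chromosomes. Host cells as their source cannot be told from these tumours: across the 9 KO tumours their level and the Y-linked score had a Pearson's r of 0.642 (exact permutation p = 0.0580, adjusted 0.116) and a Spearman's rho of 0.517 (exact permutation p = 0.162, adjusted 0.162), and r was -0.0946 without the 2 farthest tumours, so that the relation rests on those. Common ancestry of the KO lines and loss of IRE1α cannot be told apart for the 7 genes, because there is 1 WT line.

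The score of type I interferon-stimulated genes was higher in KO tumours by 0.49 (95% interval 0.23 to 0.75). Leukocyte content as the whole cause is argued against, since the difference was 0.46 (0.21 to 0.70) with a leukocyte covariate, as is host cell content, with 0.45 (0.20 to 0.70) with the Y-linked covariate. Without WT tumours 1 and 4 it was 0.56 (0.19 to 0.94). The state of the host cells, and line origin, were not tested and stay open.

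Of 100 splits of the tumours into 4 and 9, drawn from 715, only the real 1 called 518 genes, the highest other calling 7, so chance among single tumours can be excluded for that count. Chance between lines is not covered, since WT is 1 line, and 0 genes passed with libraries summed per line and 70 with the line as a random block. For the lists, 40 of 100 splits gave as many as the real 13, the highest other giving 23, so chance cannot be excluded. Of 100 splits of the 9 KO tumours into groups of 3, drawn from 280, only the real 1 called 427 genes, the highest other calling 77.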

How the results depend on the processing

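Settings chosen after seeing the data were the Y-linked covariate, the fits without WT tumours 1 and 4, the interaction without KO3 and list scores with WT tumours 3 and 4 as 1 unit. No named gene and no list that passed in the main fit changed direction under any alternative run where it was tested. Directions were not compared for those that did not pass in the main fit. The F tests among lines have no direction. Causes were not tested unless stated. For KO against WT cells (1808 genes) the count was 4780 with the lines as groups, where line spread leaves the error, 38 with libraries summed per line (fewer samples), 601 with the line as a random block, 1162, 1137 and 4315 without KO1, KO2 and KO3, and 378 to 2221 leaving out each library. For KO against WT tumours (518) it was 1103 by DESeq2, 332 with no filter, 1073 with the lines as groups, 0 with libraries summed per line, 70 with the line as a random block, 297 and 123 without KO1 and KO2, 246 with WT tumours 3 and 4 summed, 89 without WT tumours 1 and 4, and 154 to 594 leaving out each library. For the interaction (146) it was 325 by DESeq2, 229 with weights per setting, 96 without WT tumours 1 and 4, 543 without KO3, and 42 to 192 leaving out each library. For line differences it was 2271 in cells with the length-scaled table and 2094 to 4247 leaving out each library, and in tumours 1286 by DESeq2 and 128 to 1095. WT tumours against cells gave 3853 to 8115. With an estimated correlation 2 lists passed in cells, 0 in tumours and 0 for the interaction; fry gave 4 in tumours and 0 for the interaction. Leaving out each library gave 5 to 6, 10 to 15 and 10 to 13 lists, and without KO1 8 lists passed in tumours. At an adjusted p of 0.1 cells and tumours shared 411 calls, against 191.

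Replicate numbers shared between groups did not pair the libraries. The correlation of same-numbered deviations ran from -0.0515 to 0.150 in cells and from -0.394 to 0.164 in tumours. Medians were 0.0138 in cells and -0.0150 in tumours, against -0.0138 and 0.0270 for other numbers. With 2 libraries per cell group, the values for other numbers in cells are the same-numbered ones with the sign reversed. They are no separate comparison there. With the replicate block 1310 genes passed in cells, 98 in tumours, 68 for the interaction, and 3637 and 387 for line differences in cells and tumours, with 5, 14 and 13 lists.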

Other observations

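The lists below were fixed before and no test was added for them. In KO cells neither IRE1-dependent decay substrates (2 of 8 fell), MHC class I genes (2 of 19 fell), MYC targets (1 of 23 fell) nor p53 targets (1 rose and 1 fell of 13) passed as lists, with adjusted p by camera of 0.189, 0.165, 0.695 and 0.586. By fry, IRE1-dependent decay substrates were lower with an adjusted p of 0.0178, as were housekeeping genes with 0.00807. In KO tumours MHC class II genes, dendritic cell markers, endothelial markers, fibroblast and matrix genes and regulatory T cell and checkpoint genes had no member past the threshold, with adjusted p by camera of 0.0806, 0.110, 0.136, 0.4999 and 0.270. B2m and H2-K1 of MHC class I had log2 fold changes of -0.75 and -0.50 in KO cells and -0.15 and 0.02 in KO tumours, none of which passed. Ptprc and Cd274 did not pass in KO tumours either, with values of 0.38 and -0.19. In cells B2m and H2-K1 did differ among the KO lines (adjusted p = 4.69e-05 and 0.000195 by edgeR's F test). Relative to WT cells, B2m was at -1.13, -1.08 and -0.24 log2 in KO1, KO2 and KO3, and H2-K1 at -0.45, -0.99 and -0.18. Skeletal muscle markers in KO tumours had a negative median of -1.78 although camera's direction was up, with an adjusted p of 0.569 by camera.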
